A study of Mus musculus with 28 samples.

How the data were processed

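RNA sequencing of CD3-positive T cells, sorted magnetically from mouse spleen, was deposited as 1 file per mouse for 28 mice in 5 groups. Each deposited file holds expected counts (estimated fragment counts per gene, named here expected_counts) for 55413 Ensembl gene IDs. Between 21.3% and 25.0% of the values above 0 in a library were fractional, with a mean of 23.4%, so the values are not whole read counts. Per the submitters' processing notes, the authors used Trimmomatic 0.39, STAR 2.7.5a, Cufflinks 2.1.1 and Cuffdiff with the mouse build GRCm39. Which of these tools made the counts, the annotation release and the strand setting are not given in the sources used here. The deposited expected counts were not scaled to a common total.

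The expected counts were rounded to whole numbers and joined by gene ID. A reference annotation (GENCODE M21, build GRCm38) was used only to give symbols and chromosome membership, and 52082 of the 55413 IDs (94.0%) matched it. The other 3331 IDs kept their ID and stayed in every test, and they held between 0.15% and 1.38% of a library's counts. No coordinates are given, because the annotation is of another build than the deposited counts. Total counts ran from 4286885 to 15696529 per library. A count of 0 allows up to 3 counts, which is 0.191 to 0.7 CPM (counts scaled to library size) depending on the library. This floor covers counting error only, while the intervals given below are over mice. No pair of libraries was close enough to be a repeat of the same library, since the lowest chi-square per gene of any pair was 3.92.

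Groups came from the labels. Differences were tested with edgeR 4.0.16 (quasi-likelihood, robust, two-sided) in R 4.3.3 on all 28 libraries in 1 fit, with TMM scaling and the filterByExpr filter by group, which left 17182 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison are called. Each of the 4 treated groups was compared with the untreated group, and 4 comparisons were made among treated groups. An interaction contrast asked whether adding rapamycin to the carrier differed from giving free rapamycin to untreated mice. Fold changes are given on the log2 scale with the standard error of the fit, and levels as mean CPM with the standard deviation (SD) over libraries. Mice were taken as separate replicates, since the labels pair none of them.

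Lists of genes for T cell states, metabolism, signalling and the other cells of the spleen, 39 in all, were written before the data were examined, as were the comparisons, tests, the rule for named genes and most alternative settings. Each list was tested with camera (limma 3.58.1, two-sided, preset correlation of 0.01 between genes) on log2 CPM with a prior count of 2, adjusted over all 312 pairs of list and comparison. The tests were repeated with a correlation estimated from the data. After these results were seen, an exact two-sided permutation test of each list's mean log2 CPM per library was added. It used only genes present in every library, because the counts of an oral library stop early, and so left out the MHC class II list, all of whose genes lie in the missing part. For each list the number of its genes called over all genes stands beside the number adjusted over the list alone. Of the list genes, 5 symbols matched no ID.

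Named genes were picked by a fixed rule. In each comparison these were called genes with at least 2 CPM on average and an official symbol, up to 10 with the largest rise and up to 10 with the largest fall. Where fewer than 3 passed, the 5 with the smallest p were taken. Up to 4 genes with the smallest p were taken per called list, with a set of lineage and pathway genes in every comparison. Genes outside the rule are said to be chosen after their values were seen. The log2 ratio of Cd4 to Cd8a counts was compared between groups by two-sided exact permutation, adjusted over 8 comparisons.

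Alternatives were DESeq2 size factors in edgeR, no low-count filter, DESeq2 1.42.0, limma voom with sample quality weights, fits of the compared groups only, a block for replicate number, 3 covariates (the mean log2 CPM of the B cell, monocyte and macrophage, and red cell lists), a library size without immunoglobulin, haemoglobin and mitochondrial genes, and leaving out each library in turn. Fits without libraries that stood apart were chosen after seeing the data. Overlap between comparisons that share the untreated mice was set beside 20 simulations with unchanged groups and beside 70 ways of giving 3 of the 7 untreated mice to one comparison and 4 to the other. Group labels were also redealt, 60 times per comparison for genes and 100 times for lists.

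The fits were tested on simulated data in which 100 genes per fold were changed among 17148 to 17158 genes. At a 4-fold change edgeR recovered 68% of the changed genes in the comparison of the loaded carrier with untreated mice and 50% in that with the empty carrier, and at a 2-fold change 30% and 17%. It made 6 and 3 false calls in these comparisons, and DESeq2 made 25 and 31. A 2-fold shift of the mitosis list was called in 4 of 4 comparisons with the loaded carrier under both correlations, with 0 of 304 other pairs called by camera. The simulated genes were drawn independently of one another. These values therefore do not measure how often camera calls lists by chance in libraries whose genes vary together. With the real libraries and redealt labels, camera called a median of 95 pairs of list and comparison. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the ratio tests and figures. Raw reads were not available, so alignment and counting were not repeated.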

Results

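The series measured gene expression in CD3-positive spleen T cells of male C57BL/6J mice, 8 to 12 weeks old, after 11 doses over 11 days. Untreated mice (NT, n = 7) were compared with mice given empty polymersomes (PS, n = 4), rapamycin suspended in 0.2% carboxymethylcellulose (R, n = 6), oral rapamycin (RO, Rapamune, n = 6) or rapamycin-loaded polymersomes (rPS, n = 5). PS, R and rPS were injected under the skin. Polymersomes are nanoscale vesicles of a poly(ethylene glycol)-poly(propylene sulfide) polymer, and rapamycin inhibits the kinase mTOR after binding Fkbp1a. The rapamycin dose was 1 mg/kg in all 3 drug groups, and no group received the cellulose vehicle alone. The series text speaks of single cells, but the deposit holds 1 count file per mouse. Total counts per library were 5016232 to 15696529 in NT, 5926263 to 9139948 in PS, 5137057 to 8844195 in R, 4721526 to 14153508 in RO and 4286885 to 9008499 in rPS.

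Some libraries held far fewer T cell transcripts than the rest. In 6 libraries (NT replicates 3, 4, 7 and 8, R replicate 3 and RO replicate 3) Cd3e, a chain of the T cell receptor complex, lay between 9.58 and 46.9 CPM, against 76 to 471 CPM in 21 others. Lyz2, the lysozyme of myeloid cells, lay between 1870 and 3720 CPM in these 6 and between 18.9 and 693 CPM in the others. S100a8, a calcium-binding protein of neutrophils, was at 13.1 to 235 CPM against 0.518 to 15.1 CPM, and Ighm, the heavy chain of immunoglobulin M, at 2320 to 13000 CPM against 710 to 4660 CPM. These 6 were set apart because their mean log2 CPM was lower in the T cell receptor list than in the monocyte and macrophage list. NT replicate 5 just missed this cut (5.93 against 5.9), with Cd3e at 76 CPM, Lyz2 at 693 CPM and S100a8 at 15.1 CPM. The first principal axis of expression held 43.5% of the variance. RO replicate 7 listed 0 for every gene beyond a point on chromosome 12 and on 10 further chromosomes, 5251 of the 17182 tested genes (30.6%). These 7 libraries were left out together as an alternative chosen after seeing the data, and the values without them are given below as "without the 7 libraries". NT replicate 5, close to the cut, is 1 of the 3 NT libraries left in that fit.

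**Figure D1:**
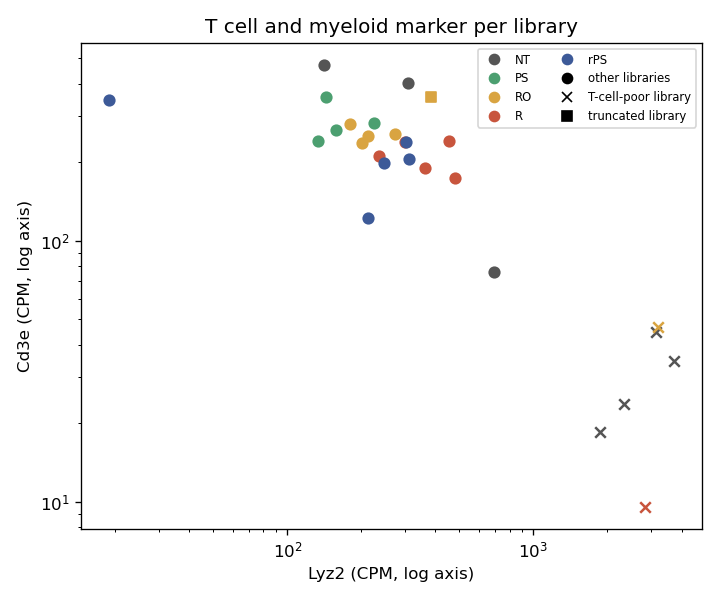
Level of the T cell gene Cd3e (vertical axis, CPM, log scale) against the myeloid gene Lyz2 (horizontal axis, CPM, log scale), 1 point per library, coloured by group. The 6 libraries drawn as crosses lie at 9.58 to 46.9 CPM of Cd3e and 1870 to 3720 CPM of Lyz2, and the square is the library whose counts stop on chromosome 12.

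Malat1 (ENSMUSG00000092341.4), an abundant nuclear RNA, and mt-Rnr2 (ENSMUSG00000064339.1), a mitochondrial ribosomal RNA, were listed at 0 in all 7 NT libraries and in RO replicate 7. In the 20 other libraries Malat1 lay between 15693 and 27818 CPM and mt-Rnr2 between 1854 and 21836 CPM. Both are among the calls of every comparison with NT, and no fitted fold change is given for them. The neighbouring mitochondrial gene mt-Rnr1 had at least 15933 counts in each NT library.

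Loaded polymersomes against no treatment compared the whole formulation with NT, and genes of cell division were lower. NT held T-cell-poor libraries and listed Malat1 and mt-Rnr2 at 0. Differences from NT, here and below, therefore need not come from the treatment alone. Of the 23 genes of the mitosis list, 22 fell over all genes tested and 23 adjusted over the list alone, with a median log2 fold change of -1.96. Top2a, which untangles DNA before chromosomes part, went from 128 ± 51.1 CPM (SD, n = 7) to 22.2 ± 8.83 CPM (n = 5), a log2 change of -2.53 ± 0.31 (SE, adjusted p = 7.0e-05). Cdk1, the kinase that starts mitosis, changed by -2.51 ± 0.36 (adjusted p = 0.00033), and Mki67, a marker of dividing cells, by -2.03 ± 0.37 (adjusted p = 0.0018). Pclaf, which binds the replication clamp, fell as well, at -2.88 ± 0.23. Camera gave the list an adjusted p of 5.26e-25, and adjusted p = 0.159 with an estimated correlation. The list for S phase and DNA replication had 8 of 26 genes lower (9 adjusted over the list alone), among them Rrm2, a subunit of ribonucleotide reductase, at -1.92 ± 0.37, with adjusted p = 0.54 with an estimated correlation. The mitosis list had 15 called genes and a median of -1.52 without the 7 libraries, and the S phase list 4 called genes.

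Interferon-stimulated genes also fell in rPS against NT. Of 28 genes in that list 15 fell (25 adjusted over the list alone), with a median log2 fold change of -1.12. Xaf1, an interferon-induced gene of cell death, went from 27.5 ± 6.25 CPM (SD, n = 7) to 10.5 ± 1.92 CPM (n = 5), a log2 change of -1.38 ± 0.19 (adjusted p = 0.00025). Oas3, a sensor of double-stranded RNA, changed by -2.22 ± 0.43 (adjusted p = 0.0029). Camera gave the list an adjusted p of 1.78e-13, and adjusted p = 0.283 with an estimated correlation. The interferon median was -0.78 without the 7 libraries, with 12 genes called and adjusted p = 0.00726 with an estimated correlation, in a range of 1.35e-17 to 0.283 over 8 alternatives.

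Cytotoxic and plasma cell genes were lower in rPS as well. In the effector and cytotoxic T cell list 9 of 30 genes fell (14 adjusted over the list alone). Klrg1, a receptor of differentiated effector cells, changed by -2.56 ± 0.45, and Gzmb, a granule protease that kills target cells, by -2.55 ± 0.62 (adjusted p = 0.0014 and 0.011). The list passed camera (adjusted p = 1.08e-06, and adjusted p = 0.283 with an estimated correlation). In the natural killer (NK) cell list, 5 of whose genes stand in other lists too, 15 of 17 genes fell (15 adjusted over the list alone). Ncr1, an activating receptor of NK cells, went from 25.3 ± 12.1 CPM (SD, n = 7) to 4.86 ± 2.6 CPM (n = 5). For that list adjusted p = 0.159 with an estimated correlation, and without the 7 libraries 10 genes were called with adjusted p = 0.0486 with an estimated correlation, in a range of 5.3e-12 to 0.159 over 8 alternatives. In the plasma cell list 10 of 14 genes fell (12 adjusted over the list alone, adjusted p = 0.441 with an estimated correlation). They included Igkc, the constant part of the kappa light chain, at -2.47 ± 0.45 and Jchain, which joins immunoglobulin units, at -2.18 ± 0.46. Of the plasma cell genes 5 were called without the 7 libraries.

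Myeloid genes were lower in the same comparison, in which 4 of the 7 NT libraries were among the T-cell-poor ones. All 18 neutrophil genes fell in rPS against NT, with a median of -4.54, and S100a8 changed by -6.36 ± 1.19. In the monocyte and macrophage list 7 of 19 genes fell (10 adjusted over the list alone), including Lyz2 at -3.1 ± 0.99, and in the dendritic cell list 6 of 15 (9 adjusted over the list alone). With an estimated correlation these 3 lists had an adjusted p = 0.57, 0.683 and 0.57. Without the 7 libraries the neutrophil median was -0.97 with 1 gene called, and that of the monocyte and macrophage list -0.39 with 0 called by edgeR. The T cell receptor list had a median of 0.56 with 0 of 25 genes called by edgeR (adjusted p = 0.737 with an estimated correlation), and -0.24 without the 7 libraries. Genes that rose included Nop56, a core protein of ribosome assembly, at 0.73 ± 0.15 (adjusted p = 0.0039), 1 of 6 of the 26 ribosome biogenesis genes called higher (8 adjusted over the list alone, adjusted p = 0.706 with an estimated correlation). The median of that list was 0.43, 0.26 with 3 called without the 7 libraries, and 0.14 with 0 called by edgeR with 3 covariates from other-cell lists. Tob1, a brake on T cell division, rose by 1.06 ± 0.28, and Syt6, of the synaptotagmin family of membrane proteins, by 5.08 ± 0.77. Mtor itself, at 0.23 ± 0.1, Foxp3, the factor of regulatory T cells, and Cd3e did not pass.

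The other list calls of rPS against NT covered metabolism, stress, B cells, red pulp macrophages and naive T cells. Targets of NRF2, the regulator of antioxidant genes, had 5 of 21 genes lower (7 adjusted over the list alone), among them Prdx1, which breaks down peroxide, at -0.88 ± 0.22, with adjusted p = 0.671 with an estimated correlation. Of 29 autophagy and lysosome genes 4 fell (6 adjusted over the list alone), such as Atp6v0d1, a part of the lysosomal proton pump, at -1.23 ± 0.24, and of 28 genes of oxidative phosphorylation also 4 (4 adjusted over the list alone), such as Cox5b, a subunit of cytochrome oxidase, at -0.97 ± 0.24. Both lists had an adjusted p = 0.816 with an estimated correlation. The B cell list had 2 of 24 genes lower (1 adjusted over the list alone, adjusted p = 0.771 with an estimated correlation), Cd24a, a surface protein of immature B cells, among them at -1.28 ± 0.34. The list of red pulp macrophages had a median of -0.44 (0 of 15 called by edgeR, adjusted p = 0.816 with an estimated correlation). With the 7 libraries left out, the medians of NRF2 targets went from -0.88 to -0.25, of autophagy and lysosome genes from -0.51 to -0.05 and of red pulp macrophages from -0.44 to 0.45, with 0 called by edgeR, and the naive T cell median to 0.04. The naive T cell list had a median of 0.56, with Tob1 as the 1 of 21 called (adjusted p = 0.737 with an estimated correlation).

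In total, 2020 genes were called in rPS against NT, 987 higher and 1033 lower. There were 542 without the 7 libraries (151 higher, 391 lower), of which 345 were among the 2020, and 1959 of 1963 genes tested in both fits had the same sign. The count dropped to 1249 without NT replicate 7, 1264 without NT replicate 8, 1293 without NT replicate 3, 1109 without rPS replicate 4, 1091 without rPS replicate 5 and 944 without rPS replicate 7.

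Free rapamycin under the skin against no treatment tested the drug without the carrier, and the genes that fell included a few of mitosis and antibody secretion. Pclaf (ENSMUSG00000040204.7) went from 22.7 ± 5.25 CPM (SD, n = 7) to 5.19 ± 1.6 CPM (n = 6), a log2 change of -2.13 ± 0.21 (SE, adjusted p = 2.96e-06). Mybl1 (ENSMUSG00000025912.17), a transcription factor of dividing B cells and germ cells, changed by -2.14 ± 0.32 (adjusted p = 0.00149). Of the 23 mitosis genes 4 fell (20 adjusted over the list alone), among them Top2a at -1.63 ± 0.28 and Stmn1, which takes apart microtubules, at -1.43 ± 0.21. Of the 28 interferon genes 3 fell (16 adjusted over the list alone). Among them were Xaf1 at -0.92 ± 0.17 and Zbp1, a sensor of nucleic acids, at -0.99 ± 0.22. Both lists had an adjusted p = 0.159 with an estimated correlation. Jchain at -2.02 ± 0.42 and Igkc at -1.86 ± 0.41 were the plasma cell genes called (11 of 14 adjusted over the list alone, adjusted p = 0.283 with an estimated correlation). Syt6 rose, from 1.04 ± 1.28 CPM to 15.1 ± 8.81 CPM. The mitosis median was -0.73 without the 7 libraries, with 1 gene called and the plasma cell median -0.76 with 2.

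Other lists passed camera in R against NT with few or no genes called. The NK cell list had a median of -1.16 with 0 of 17 genes called by edgeR (11 adjusted over the list alone, adjusted p = 0.182 with an estimated correlation). The S phase list had a median of -0.47 with 0 of 26 called (9 adjusted over the list alone, adjusted p = 0.166 with an estimated correlation). The 23 genes of cholesterol synthesis all had negative fold changes, with a median of -0.36, 0 called by edgeR (1 adjusted over the list alone) and adjusted p = 0.503 with an estimated correlation. Red cell genes had a median of 1.26 (0 of 20 called, adjusted p = 0.719 with an estimated correlation), and genes of pancreatic acinar cells 2.97 (0 of 13 called, 11 adjusted over the list alone, adjusted p = 0.737 with an estimated correlation). Neutrophil genes had a median of -1.68 (0 of 18 called, adjusted p = 0.706 with an estimated correlation) and -0.25 without the 7 libraries. Without the 7 libraries, the interferon list had 8 genes called and adjusted p = 0.00142 with an estimated correlation, in a range of 6.05e-26 to 0.159 over 8 alternatives.

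The remaining list calls of R against NT covered defence, metabolism, myeloid cells, ribosomal proteins and the T cell receptor. The effector and cytotoxic list had a median of -0.43 (0 of 30 called by edgeR, 2 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). The ATF4 list of amino acid supply had a median of -0.21, glycolysis -0.25, oxidative phosphorylation -0.13, autophagy and lysosome genes -0.28 and NRF2 targets -0.48, each with 0 genes called by edgeR. With an estimated correlation these had an adjusted p = 0.502, 0.737, 0.816, 0.816 and 0.683. MHC class I genes had a median of -0.29 with 1 of 17 lower (1 adjusted over the list alone, adjusted p = 0.816 with an estimated correlation), Pdia3, which folds proteins in the endoplasmic reticulum, at -0.76 ± 0.16. Monocytes and macrophages had a median of -0.91 and dendritic cells -0.7, both with 0 called (adjusted p = 0.757 and adjusted p = 0.616 with an estimated correlation). The lists of cytosolic ribosomal proteins, at 0.05, and of the T cell receptor, at 0.16, passed as higher (adjusted p = 0.899 and adjusted p = 0.877 with an estimated correlation) and had medians of -0.34 and -0.53 without the 7 libraries. In that fit autophagy and lysosome genes were at -0.02, NRF2 targets at -0.09, glycolysis at -0.13, ATF4 targets at -0.1, monocytes and macrophages at -0.07 and dendritic cells at -0.22.

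In R against NT 50 genes were called, 4 higher and 46 lower, and 41 without the 7 libraries, 16 of them among the 50. The 4 higher genes were Malat1, mt-Rnr2, Syt6 and A530083I20Rik, the last chosen after its values were seen. The count was 21 without NT replicate 4, 155 without NT replicate 5, 92 without NT replicate 6, 15 without NT replicate 7, 20 without NT replicate 8 and 22 without NT replicate 3. It was 167 without R replicate 3, 27 without R replicate 4, 18 without R replicate 5, 13 without R replicate 6 or 7, and 20 without R replicate 2.

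Oral rapamycin against no treatment left no named gene with a fitted fold past the adjustment. Pclaf was at 11.0 ± 1.91 CPM (SD, n = 6) against 22.7 ± 5.25 CPM (n = 7), a log2 difference of -1.04 ± 0.2 that did not pass (adjusted p = 0.084). The mitosis list had a median of -1.07 with 0 of 23 genes called (22 adjusted over the list alone) and adjusted p = 0.309 with an estimated correlation. The interferon list had a median of -0.61 with 0 of 28 called (1 adjusted over the list alone), and adjusted p = 0.57 with an estimated correlation. Without the 7 libraries the interferon value was 0.0427 as an adjusted p with an estimated correlation, in a range of 2.9e-10 to 0.57 over 8 alternatives. The NK cell list had a median of -1.13 (0 of 17 called, 12 adjusted over the list alone, adjusted p = 0.295 with an estimated correlation). All 18 neutrophil genes passed adjusted over the list alone, with a median of -3.11, 0 over all genes and adjusted p = 0.57 with an estimated correlation. The T cell receptor list had a median of 0.36 (adjusted p = 0.733 with an estimated correlation). With the 7 libraries left out the medians of the mitosis, NK cell, neutrophil and T cell receptor lists were -0.63, -0.85, -1.23 and -0.26.

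Further lists passed camera in RO against NT, with 0 genes called by edgeR. The plasma cell list had a median of -1.05 (4 of 14 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation) and the effector list -0.58 (4 of 30 adjusted over the list alone, adjusted p = 0.671 with an estimated correlation). S phase genes had a median of -0.32, NRF2 targets -0.6, autophagy and lysosome genes -0.47 and naive T cell genes 0.15, with adjusted p = 0.679, 0.706, 0.816 and 0.816 with an estimated correlation. MHC class I genes had a median of -0.25 (3 of 17 adjusted over the list alone, adjusted p = 0.816 with an estimated correlation) and MHC class II genes -0.35 (adjusted p = 0.84 with an estimated correlation). All MHC class II genes are listed at 0 in RO replicate 7, and without that library the MHC class I and class II medians were 0.01 and -0.08. The medians were -0.92 for monocytes and macrophages and -0.78 for dendritic cells (adjusted p = 0.737 and adjusted p = 0.816 with an estimated correlation). With the 7 libraries left out these were -0.5 and -0.28, those of plasma cells -0.34, NRF2 targets -0.28, autophagy and lysosome genes -0.05 and naive T cells -0.13.

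In RO against NT 2 genes were called by edgeR, Malat1 and mt-Rnr2, with 1892 at an unadjusted p under 0.05. DESeq2 called 247 and limma voom with quality weights 8055. The count was 99 without NT replicate 5 and 23 without NT replicate 6.

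Empty polymersomes against no treatment tested the carrier alone. Vamp2, a protein of vesicle fusion, rose from 88.2 ± 15.8 CPM (SD, n = 7) to 187 ± 21.1 CPM (n = 4), a log2 change of 1.08 ± 0.19 (adjusted p = 0.039). Rab10os, a transcript opposite the Rab10 gene, rose by 0.96 ± 0.18 (adjusted p = 0.045). The mitosis list had a median of -0.93 with 0 of 23 called (15 adjusted over the list alone, adjusted p = 0.523 with an estimated correlation), and the interferon list -0.73 with 0 of 28 called (5 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation). Targets of NRF2, the regulator of antioxidant genes, had a median of -1.04 with 0 of 21 called (11 adjusted over the list alone, adjusted p = 0.523 with an estimated correlation). The neutrophil median was -5.04 (18 of 18 adjusted over the list alone, adjusted p = 0.523 with an estimated correlation), that of monocytes and macrophages -2.21 (12 of 19 adjusted over the list alone, adjusted p = 0.638 with an estimated correlation) and that of the T cell receptor list 0.78 (adjusted p = 0.737 with an estimated correlation). Without the 7 libraries the mitosis, interferon, NRF2, neutrophil, monocyte and macrophage, and T cell receptor medians were -0.44, -0.32, -0.41, -1.19, -0.71 and -0.14. With 3 covariates from other-cell lists the mitosis, interferon and T cell receptor medians were -0.13, -0.13 and 0.05.

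Lists of other cells and of metabolism also passed camera in PS against NT, with 0 genes called by edgeR. The NK cell list had a median of -1.5 (11 of 17 lower adjusted over the list alone, adjusted p = 0.295 with an estimated correlation), the effector list -0.83 (7 of 30 adjusted over the list alone, adjusted p = 0.538 with an estimated correlation) and the dendritic cell list -1.76 (8 of 15 adjusted over the list alone, adjusted p = 0.638 with an estimated correlation). Red pulp macrophages had a median of -1.3 and plasma cells -0.77 (3 of 14 adjusted over the list alone), both with adjusted p = 0.737 with an estimated correlation. Autophagy and lysosome genes had a median of -0.56 (9 of 29 adjusted over the list alone), glycolysis -0.49, oxidative phosphorylation -0.26 and naive T cell genes 0.45, with adjusted p = 0.737, 0.706, 0.816 and 0.757 with an estimated correlation. With the 7 libraries left out, which takes 4 of the 7 NT mice, the medians were -0.22 for autophagy and lysosome genes, -0.17 for glycolysis, -0.42 for dendritic cells, -0.34 for red pulp macrophages, -0.15 for plasma cells, -0.87 for NK cells, -0.8 for the effector list and 0.03 for naive T cells.

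In PS against NT 5 genes were called, all higher, namely Malat1, mt-Rnr2, Vamp2, Rab10os and Gm45902 (0.92 ± 0.17), the last chosen after its values were seen. With 4057 genes at an unadjusted p under 0.05, the count by edgeR was 851 without the truncated oral library (429 higher, 422 lower) and 2 without the 7 libraries, and 76% rather than 100% were higher when library size left out immunoglobulin, haemoglobin and mitochondrial genes. It was 1142 without NT replicate 5, 506 without NT replicate 6, 3 without NT replicate 8, and 2 without any of NT replicates 2, 3, 4 and 7 or PS replicates 1, 3, 4 and 5.

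Loaded against empty polymersomes isolated the drug at a matched carrier and route, with no T-cell-poor library in either group. Pclaf fell from 14.1 ± 1.65 CPM (SD, n = 4) to 3.04 ± 0.901 CPM (n = 5), a log2 change of -2.2 ± 0.25 (adjusted p = 4.49e-05). Mybl1 fell from 5.62 ± 2.21 to 1.18 ± 0.362 CPM, a change of -2.27 ± 0.38 (adjusted p = 0.0176). Both other called genes were chosen after their values were seen. Rgs13, a G protein regulator of germinal centre B cells, changed by -5.76 ± 0.97 and Col5a3, a collagen chain, by -6.39 ± 0.96. Both averaged under 2 CPM over all libraries, so their fold changes, here and below, rest on low counts. The mitosis list had a median of -1.09 with 0 of 23 genes called by edgeR (14 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation), and its mean log2 CPM per library differed by -1.10 (exact permutation p = 0.0159, adjusted p = 0.125). Top2a was at 61.2 ± 8.46 CPM in PS and 22.2 ± 8.83 CPM in rPS. Syt6 differed by 4.92 ± 0.97 and did not pass (adjusted p = 0.066). The interferon list had a median of -0.5 with 0 of 28 called (4 adjusted over the list alone, adjusted p = 0.405 with an estimated correlation). With 3 covariates from other-cell lists edgeR called 4 mitosis genes (median -1.38) and 3 interferon genes (median -0.63). With the replicate block it called 0 in either list.

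Several lists of other cells and of growth passed camera in rPS against PS, each with 0 genes called by edgeR. The plasma cell median was -0.79 (2 of 14 adjusted over the list alone, adjusted p = 0.471 with an estimated correlation) and the B cell median -0.37 (adjusted p = 0.638 with an estimated correlation). The NK cell median was -0.63 (1 of 17 adjusted over the list alone, adjusted p = 0.371 with an estimated correlation). With 3 covariates from other-cell lists the NK cell median was -0.23 and the plasma cell median stayed at -0.79. Red cell genes had a median of 1.34, with 20 of 20 positive and a difference of 0.53 in the mean per library (exact permutation p = 0.532), and pancreatic acinar genes 3.38, with adjusted p = 0.766 and adjusted p = 0.441 with an estimated correlation. Cytosolic ribosomal proteins had a median of 0.26 (adjusted p = 0.816 with an estimated correlation), and components of the mTOR pathway 0.12 (1 of 28 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation). Ribosome biogenesis genes had a median of 0.19 (adjusted p = 0.706 with an estimated correlation), glucocorticoid response genes 0.5 and effector genes -0.29 (adjusted p = 0.57 with an estimated correlation for both). S phase genes had a median of -0.23 and cytokine receptor genes 0.18 (1 of 32 adjusted over the list alone), with adjusted p = 0.57 and adjusted p = 0.737 with an estimated correlation. Bcl2, a survival protein, was at 368 ± 26.9 CPM (SD, n = 4) in PS and 841 ± 268 CPM (n = 5) in rPS, a difference of 1.19 ± 0.32 that did not pass (adjusted p = 0.37).

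The 4 genes called in rPS against PS were all lower, with 617 at an unadjusted p under 0.05, and all 4 were among the 41 called without the 7 libraries (12 higher, 29 lower), where the interferon list had adjusted p = 0.00969 with an estimated correlation in a range of 3.23e-20 to 0.405 over 8 alternatives. The count was 14 without the truncated oral library, 11 without rPS replicate 4, and 2 without rPS replicate 5 or 7 or without PS replicate 1, 3 or 4.

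Loaded polymersomes against free rapamycin at the same dose and route compared the carrier form with the plain drug. The largest separations by p did not pass. Kif18a, a motor protein of the spindle, was at 2.89 ± 0.992 CPM (SD, n = 5) in rPS and 6.18 ± 1.25 CPM (n = 6) in R, a log2 difference of -1.08 ± 0.22 (adjusted p = 0.19). Pclaf was at 3.04 ± 0.901 CPM in rPS and 5.19 ± 1.6 CPM in R. The mitosis list had a median of -0.91 (-0.5 with 3 covariates from other-cell lists) with 0 of 23 called (14 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation), and Cdk1 differed by -1.41 ± 0.36. The B cell median was -0.69 (adjusted p = 0.57 with an estimated correlation), the NK cell median -0.96 (2 of 17 adjusted over the list alone, adjusted p = 0.283 with an estimated correlation), the neutrophil median -2.84 (adjusted p = 0.679 with an estimated correlation) and the red cell median -1.03 (adjusted p = 0.737 with an estimated correlation). Ribosome biogenesis genes had a median of 0.29 (1 of 26 adjusted over the list alone, adjusted p = 0.601 with an estimated correlation). The other list calls were the T cell receptor at a median of 0.56, naive T cells at 0.31, the effector list at -0.38, interferon genes at -0.32 and NRF2 targets at -0.40, with adjusted p = 0.737, 0.737, 0.54, 0.757 and 0.816 with an estimated correlation. Monocytes and macrophages had a median of -0.89, dendritic cells -0.80 and red pulp macrophages -0.03 (adjusted p = 0.737, 0.737 and 0.821 with an estimated correlation). With the 7 libraries left out the medians were -1.0 for neutrophils, -0.25 for monocytes and macrophages, -0.22 for dendritic cells, -0.08 for interferon genes, -0.16 for NRF2 targets and 0.33 for the T cell receptor list. EdgeR called 0 genes, with 1381 at an unadjusted p under 0.05, DESeq2 40 and limma voom 0. In simulated data with 100 changed genes per fold, DESeq2 made 30 false calls in this comparison beside 41 and 74 recovered genes. That number of false calls does not carry over to the 40 real calls. The count by edgeR was 14 without rPS replicate 1 and 18 without rPS replicate 2.

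Free rapamycin under the skin against oral rapamycin compared the routes, with formulations that differ too. Pclaf differed by -1.09 ± 0.21 and Myb, a factor of blood cell growth, by -0.86 ± 0.16, and neither passed (adjusted p = 0.11 for both). The interferon list had a median of -0.29 with 0 of 28 called (2 adjusted over the list alone, adjusted p = 0.679 with an estimated correlation) and adjusted p = 0.0427 with an estimated correlation without the 7 libraries, in a range of 2.77e-10 to 0.815 over 8 alternatives. Red cell genes had a median of 2.09 with 0 of 20 called (12 adjusted over the list alone, adjusted p = 0.446 with an estimated correlation). The mitosis median was -0.05 (adjusted p = 0.821 with an estimated correlation) and -0.57 with 3 covariates from other-cell lists. Cholesterol synthesis genes had a median of -0.19, ATF4 targets -0.1, S phase genes -0.11 and co-inhibitory receptors -0.21 (adjusted p = 0.634, 0.459, 0.57 and 0.673 with an estimated correlation). The T cell receptor list had a median of -0.25, plasma cells -0.53, MHC class II genes 0.39, neutrophils 1.7 and pancreatic acinar genes 1.42 (adjusted p = 0.816, 0.816, 0.737, 0.811 and 0.737 with an estimated correlation). The MHC class II genes are listed at 0 in RO replicate 7, and without that library their median was 0.12. EdgeR called 0 genes, with 432 at an unadjusted p under 0.05, DESeq2 13 and limma voom 131, and edgeR called 2 without R replicate 3.

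Loaded polymersomes against oral rapamycin set the carrier form against the clinical form at an equal dose. Pclaf was at 3.04 ± 0.901 CPM (SD, n = 5) in rPS and 11.0 ± 1.91 CPM (n = 6) in RO, a log2 change of -1.85 ± 0.23 (adjusted p = 0.000361). Col5a3 (-6.42 ± 0.92), Rgs13 (-5.65 ± 0.94) and Igkv12-46, a kappa variable segment (-2.77 ± 0.46), were the other called genes and were chosen after their values were seen. Mybl1 differed by -1.77 ± 0.36 and Syt6 by 3.69 ± 0.76 without passing (adjusted p = 0.089 for both). The mitosis list had a median of -0.85 with 0 of 23 called (9 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation). The interferon list had a median of -0.69 (5 of 28 adjusted over the list alone, adjusted p = 0.441 with an estimated correlation) and, without the 7 libraries, adjusted p = 0.0275 with an estimated correlation, in a range of 4.48e-13 to 0.441 over 8 alternatives. The pancreatic acinar list had a median of -0.01 and a mean of 0.0, while its test pointed higher (adjusted p = 0.877 with an estimated correlation). The NK cell median was -0.96 (2 of 17 adjusted over the list alone), that of plasma cells -0.76 (1 of 14), of B cells -0.41 and of effector genes -0.35, with adjusted p = 0.295, 0.679, 0.719 and 0.309 with an estimated correlation. Ribosome biogenesis genes had a median of 0.25, glucocorticoid response genes 0.32, red cell genes 1.03 and S phase genes -0.18 (adjusted p = 0.737, 0.737, 0.877 and 0.706 with an estimated correlation). Dendritic cells were at -0.65, monocytes and macrophages at -0.92 and red pulp macrophages at -0.12 (adjusted p = 0.57, 0.821 and 0.816 with an estimated correlation). These 3 medians were -0.19, 0.17 and 0.49 without the 7 libraries, and those of NK cells -0.4 and red cell genes 0.6. The 4 calls were all lower, with 1170 genes at an unadjusted p under 0.05. The count was 8 without the 7 libraries, 9 without rPS replicate 1, 32 without rPS replicate 2 and 2 without rPS replicate 5.

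The interaction contrast asked whether the drug acted differently inside the carrier. Leng8 was at 317 ± 49.7 CPM (SD, n = 7) in NT, 446 ± 73.0 CPM (n = 6) in R, 479 ± 33.9 CPM (n = 4) in PS and 312 ± 27.1 CPM (n = 5) in rPS, an interaction of -1.11 ± 0.19 (SE, adjusted p = 0.0272). Malat1 and mt-Rnr2 were the other calls of 3, with 557 genes at an unadjusted p under 0.05 and 11 called by DESeq2. In simulated data with 100 changed genes per fold, DESeq2 made 19 false calls here beside 18 and 44 recovered genes. That number of false calls does not carry over to the 11 real calls. Leng8 was not called without the 7 libraries.

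**Figure D2:**
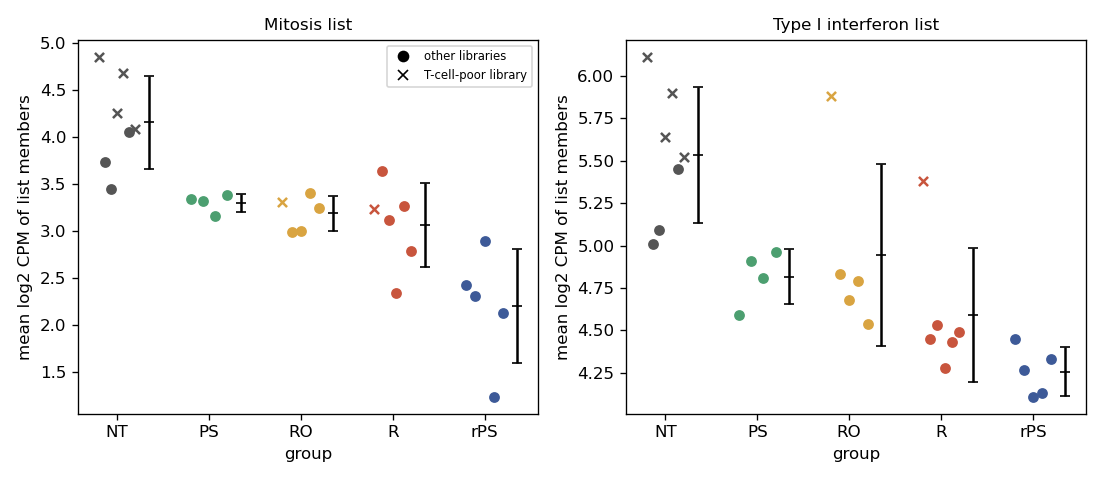
Mean log2 CPM (vertical axes) of the 23 mitosis genes (left) and 28 type I interferon genes (right) by group, 1 point per library, with the mean and SD as bars and the T-cell-poor libraries as crosses; RO replicate 7 is left out. Mitosis means run from 4.16 in NT to 2.20 in rPS and interferon means from 5.53 to 4.26, with PS at 3.30 and 4.82.

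Across all lists, camera called 121 of 312 pairs of list and comparison. With the group labels redealt, the median was 95 calls. None of the 121 calls held with an estimated correlation, and fry called 16. Without the 7 libraries 7 pairs passed with an estimated correlation, namely the interferon list in rPS, R and RO against NT, in rPS against PS and RO and in R against RO, and the NK cell list in rPS against NT. In the exact permutation of list means, 72 of 304 pairs had an unadjusted p under 0.05 and 0 passed the adjustment, with a smallest adjusted p of 0.064.

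The genes called with loaded polymersomes and with free rapamycin overlapped. Leaving out Malat1 and mt-Rnr2, 47 genes were called in both rPS against NT and R against NT (2 higher, 45 lower), where the product of the counts over the 17180 genes gives 0.11 and 2.77. The shared genes included Pclaf, Mybl1, Top2a and Rgs13. Log2 fold changes correlated across genes at r = 0.77, against a mean of 0.43 in simulations with unchanged groups and shared controls. The covariance was 0.395 against a simulated 0.093. The simulations drew genes independently, so they hold no shared shift in the cell content of the NT mice, which could raise r and the number shared. With separate NT mice for each comparison (3 and 4) the median r was 0.54, from -0.16 to 0.71, and the median number shared was 9.5. Genes are not independent replicates. The pair that shares no mice, rPS against PS and R against NT, had 4 genes in common where the product gives 0.01, with r = 0.23 (simulated mean 0). They were Pclaf, Mybl1, Rgs13 and Col5a3, of which Rgs13 and Col5a3 averaged under 2 CPM. For empty polymersomes and rPS, each against NT, 1 gene was shared (Gm45902) and r was 0.86, with a covariance of 0.733 against 0.093 and a divided-control r of 0.72.

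The balance of CD4 and CD8 T cell transcripts differed with free rapamycin. The log2 ratio of Cd4 to Cd8a, the co-receptors of helper and cytotoxic T cells, was -1.44 ± 0.65 (SD, n = 6) in R and -0.66 ± 0.27 (n = 7) in NT, a difference of -0.78 (two-sided exact permutation p = 0.00291, adjusted p = 0.0233). In RO the difference was -0.67 (exact p = 0.0186, adjusted p = 0.0746), in rPS -0.48 (exact p = 0.25, adjusted p = 0.5) and in PS -0.27 (exact p = 0.152, adjusted p = 0.404). Among the treated groups it was -0.21 for rPS against PS, 0.30 for rPS against R, 0.20 for rPS against RO and -0.10 for R against RO, each with an exact permutation adjusted p of 0.771. The call for R was lost (adjusted p from 0.0505 to 0.0866) without any 1 library of R or NT other than R replicate 3, and with Cd8b1 added to Cd8a (-0.86, adjusted p = 0.133). The difference was -0.78 without the 6 T-cell-poor libraries (adjusted p = 0.357), where the smallest possible exact permutation p of 0.0179 was not reached. With the replicate block it was -0.73 (adjusted p = 0.25). There the exact p was the smallest possible, 0.0312, which leaves little room to pass over 8 comparisons. Without RO replicate 3 or RO replicate 5 the difference for RO passed, at -0.82 and -0.77.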

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

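The tests of other cells, of the carrier, of the 0 counts, of red cells and of B cells were chosen only after the results were seen. So were the redeals for the gene lists and for rPS against NT, and the other redeals were chosen before. The predictions for rapamycin and for germinal centre genes were written before those tests. The patterns they address, and the fit without the 7 libraries used for some of them, came from the data.

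Single libraries lay far from the rest of their group in the mean log2 CPM of a gene list, in 35 of the 220 groups of values tested, where about 1 in 20, or 11, would do so by chance. R replicate 3 was the farthest in 14 lists. It was low in T cell genes, with the T cell receptor complex at 4.04, T cell receptor activation at 4.21, the naive programme at 6.02, cytokine receptors at 6.12, regulatory T cells at 3.07, gamma delta T cells at 2.20 and ribosome biogenesis at 5.30. The B cell list was low too, at 6.46, where the other R libraries had 7.79 to 8.23. It was high in monocytes and macrophages (7.77), neutrophils (6.06), dendritic cells (5.79), NRF2 targets (6.27), autophagy and lysosome genes (6.80) and interferon genes (5.38). RO replicate 3 stood apart in 12 lists. It was low in the T cell receptor complex (5.59), the naive programme (6.59) and ribosome biogenesis (5.69). It was high in the other 9, with monocytes and macrophages at 8.02, neutrophils at 4.18, NRF2 targets at 6.46, autophagy and lysosome genes at 6.90, cholesterol synthesis at 4.66, effector T cells at 4.50, glycolysis at 6.79, pancreatic acinar genes at 4.90 and interferon genes at 5.88. Both are T-cell-poor libraries.

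In rPS replicate 5 the low lists were neutrophils at -0.18, dendritic cells at 2.46, plasma cells at 3.01 and autophagy and lysosome genes at 5.57, and the high lists co-inhibitory receptors at 5.01 and cytokine receptors at 7.24. The remaining values were a high MHC class I list at 8.32 in rPS replicate 2, a low MHC class II list at 8.26 in RO replicate 5 and high red cell genes at 4.36 in PS replicate 5. The interaction of drug and carrier drew attention as a difference between groups for Malat1 (adjusted p = 0.000288), mt-Rnr2 (adjusted p = 0.000705) and Leng8 (adjusted p = 0.0272).

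The first pattern is the 2020 genes called in rPS against NT beside the 4 in rPS against PS. Other cells in the T-cell-poor NT libraries could account for part of it, but the test made cannot decide this. The fold changes of these genes without the 7 libraries had a median ratio of 0.71 to those with them (0.77 for higher and 0.64 for lower genes, 1961 genes). The genes were picked in the fit with those libraries, so some shrinkage would follow from leaving out any mice used to pick them. Against rapamycin as the account of the whole set, 26.8% of the genes had the same sign in R against PS, and 35.4% of the genes not called. For the carrier, 68.0% had the same sign in PS against RO and 60.3% of the genes not called. Other cells and the carrier cannot be told apart, because PS against RO also differs in the drug. The comparison of rPS with R matches the drug and uses no NT mice, but shares the rPS mice with the pattern. There edgeR called 0 genes (1381 at an unadjusted p under 0.05), limma voom 0 and DESeq2 40. In simulated data with 100 changed genes per fold, DESeq2 made 30 false calls there beside 41 and 74 recovered genes. That number of false calls does not carry over to the 40 real calls.

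The second pattern is Malat1 and mt-Rnr2 listed at 0 in all NT libraries. The neighbouring mt-Rnr1 had at least 15933 counts in each of them, which would fit a difference in the authors' processing of these libraries. Lower depth is argued against, since an NT library at the lowest Malat1 level seen elsewhere would hold at least 78721 counts. A loss of the transcripts in the mice would have to exceed 26240-fold for Malat1, set against a floor of 3 counts per library, and stays open because the reads were not at hand. A difference in processing could also have moved other genes in every comparison with NT, the 2020 genes of rPS against NT included, which was not tested.

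The third pattern is the lower mitosis list in rPS against PS, with a median of -1.09. A matching fall in red cell precursors is argued against as the whole account, since the red cell score per library, less the mitosis score, was 1.63 higher in rPS (95% interval over mice 0.60 to 2.67), although both scores correlated within rPS (r = 0.98, n = 5). Fewer B cells of all kinds stay open, with a gap to the mitosis score of 0.33 (95% interval -0.74 to 1.39), because the B cell score varied too much between the rPS mice. Fewer germinal centre B cells might contribute, since 7 of 7 genes of such cells had negative fold changes, with a median of -0.68. This stays open because bulk counts do not show which cells divided.

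Group labels were redealt to see what the same libraries give by chance. Chance is argued against for the 2020 genes of rPS against NT, where 1 of 60 divisions (the real one) reached the count and the highest other gave 509. For the 4 genes of rPS against PS and the 4 of rPS against RO 2 of 60 divisions reached the count, the real one included. The other division gave 67 and 175 genes, many times the real count, which points to a structure of the samples. With no adjustment over comparisons, chance stays open for so few genes. For the 5 genes of PS against NT and the 3 of the interaction 1 of 60 reached the count and the highest other gave 0, and 2 of the calls in each are Malat1 and mt-Rnr2, listed at 0 in NT. Chance could not be excluded for the 50 genes of R against NT (3 of 60, highest other 1915) and the 2 of RO against NT (5 of 60, highest other 4396), and these highest values point to a structure of the samples. For rPS against R and R against RO the real count is 0, so that 60 of 60 divisions reach it by construction and the count says nothing about chance (highest other 223 and 0). For the 121 list calls 5 of 100 redeals reached as many, with a highest other of 128 and a median of 95, so chance could not be excluded. The 17 list calls in rPS, 20 in R, 15 in RO and 15 in PS against NT were reached in 10, 1 (the real one), 27 and 29 of 100. The 14 in rPS against PS, 14 in rPS against R, 12 in R against RO and 14 in rPS against RO were reached in 39, 37, 54 and 28. The median redeal gave 11 or 12 in each comparison.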

How the results depend on the processing

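The fits without some libraries and the permutation of list means were chosen only after the results were seen, and the other settings before. The cause was not tested for any change below, except that fits of fewer groups or libraries rest on fewer samples. The truncated oral library can also reach comparisons without RO only through the joint fit. Depth and scatter limit what could be found, since in simulated data edgeR recovered 50% of 4-fold changes in rPS against PS, 68% in rPS against NT and 34% in the interaction. Of values for named genes 835 kept call and direction, 288 were weaker and 15 reversed. Leaving out single libraries kept 894 and weakened 277.

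The count of called genes depended on the tool. In simulated data DESeq2 made 25 false calls in rPS against NT, 31 in rPS against PS and 30 in rPS against R. It made 32 in rPS against RO and 19 in the interaction. EdgeR made 6, 3, 4, 6 and 1 in these. All of these arose beside 100 changed genes per fold, so their number does not carry over to the real calls. DESeq2 called 3440 in rPS against NT, 289 in R against NT, 247 in RO against NT, 2007 in PS against NT, 44 in rPS against PS, 40 in rPS against R, 13 in R against RO, 85 in rPS against RO and 11 in the interaction. Limma voom with quality weights called 6160, 7075, 8055 and 9359 in rPS, R, RO and PS against NT, 21 in rPS against PS, 131 in R against RO and 1976 in the interaction. Fits of only the compared groups called 1110 in rPS against NT, 10 in R against NT, 0 in RO against NT, 2011 in PS against NT and 0 in rPS against RO. Without the low-count filter 17 were called in R against NT and 3 in PS against NT. DESeq2 size factors gave 2 in PS against NT, and a library size without immunoglobulin, haemoglobin and mitochondrial genes gave 25.

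With 3 covariates from other-cell lists the counts were 581 in rPS, 107 in R, 4 in RO and 3 in PS against NT, 16 in rPS against PS, 3 in R against RO and 8 in rPS against RO. The same covariates without the truncated oral library gave 246 in R against NT, 5 in RO against NT, 69 in rPS against PS, 12 in rPS against R, 6 in R against RO and 14 in rPS against RO. Without the truncated library alone they were 3688 in rPS against NT, 114 in R against NT, 851 in PS against NT, 14 in rPS against PS and 2 in rPS against R. These comparisons hold no RO library, so the change came through the filter, scaling and spread that all groups share. The common spread between libraries (biological coefficient of variation) was 0.48 in the main fit and 0.39 without the truncated library. Without the 7 libraries the counts were 542 in rPS against NT, 2 in PS against NT, 41 in rPS against PS, 1 in rPS against R and 8 in rPS against RO. Leaving out NT replicate 5 as well gave 2554 in rPS against NT, 623 in R against NT, 618 in RO against NT and 1327 in PS against NT. It gave 90 in rPS against PS, 40 in rPS against R, 14 in rPS against RO and 63 in the interaction. Only NT replicates 2 and 6 remain untreated in that fit. They lay at 67.9 and 63.2 on the second principal axis, where the highest other library lay at 28.

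A block for the replicate number gave 625 in rPS against NT, 9 in R against NT, 2 in PS against NT, 1 in rPS against PS, 1 in rPS against RO and 0 in the interaction. The labels do not say that these numbers pair mice, and the values leave shared handling by number open. The 41 pairs with the same number had a mean correlation of 0.0752 (-0.339 to 0.802, 16 above 0.1) against -0.0119 for other pairs. Of the 28 libraries 8 correlated best with a library of their own number.

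The fold changes in rPS against NT that reversed belong to myeloid genes. With the covariates they were Ltf 0.26, Lcn2 0.13, Mpo 0.21, Ctsh 0.04 and Lyz2 0.06. When the truncated library was left out too they were Ltf 0.20, Lcn2 0.03, Mpo 0.32, Ctsh 0.03 and Lyz2 0.06. Ctsh and Lyz2 belong to the monocyte and macrophage list whose mean is a covariate, so their values near 0 follow from the fit. In the fit without the 7 libraries and NT replicate 5 the reversed values were Vcan 0.97, Ltf 1.10, Lcn2 0.04, Prtn3 0.57 and Mpo 0.91, with only NT replicates 2 and 6 left untreated.

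Camera called 121 pairs of list and comparison, 0 with an estimated correlation, 7 with it and without the 7 libraries, and 16 were called by fry. The Cd4 to Cd8a difference in R against NT was -0.86 with Cd8b1 added (exact permutation adjusted p = 0.133), -0.78 without the T-cell-poor libraries (adjusted p = 0.357) and -0.73 with the replicate block (adjusted p = 0.25). With the replicate block the exact p was the smallest possible, 0.0312, so that lost call shows no dependence on the block. Without the T-cell-poor libraries the smallest possible exact p was 0.0179 and was not reached. The limit of the test therefore does not account for that lost call, though the difference kept its size.

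Genes shared by rPS and R against NT numbered 9.5 with divided controls, 96 at an adjusted p under 0.1 and 106 without the truncated library. For rPS and PS against NT they were 0, 1144 and 693, and 0 without the 7 libraries. At an adjusted p under 0.1, 2 genes were shared by rPS and RO against NT, 2 by R and RO, 43 by R and PS (36 without the truncated library) and 1 by RO and PS. For rPS against PS with R against NT they were 7 at 0.1, 8 without the truncated library and 11 without the 7 libraries, and with RO against NT 1 at 0.1.

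Leaving out each library in turn gave 944 to 2847 genes in rPS against NT, 13 to 167 in R against NT, 2 to 99 in RO against NT, 2 to 1142 in PS against NT, 2 to 11 in rPS against PS, 0 to 18 in rPS against R, 0 to 2 in R against RO, 2 to 32 in rPS against RO, 2 to 4 in the interaction and 116 to 137 list calls. The Cd4 to Cd8a difference ran from -0.91 to -0.58 in R against NT, from -0.82 to -0.55 in RO against NT, from -0.75 to -0.15 in rPS against NT and from -0.34 to -0.16 in PS against NT.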

Other observations

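The steps between formulations were tested only after the mitosis and interferon results were seen. The prediction for germinal centre genes in R against NT was written before that test, but the fit without the 7 libraries that it uses was chosen after seeing the data.

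Some genes of germinal centre B cells, which give rise to high-affinity antibodies, fell with loaded polymersomes. In rPS against NT 4 of a set of 7 such genes were called lower. S1pr2, which holds B cells in the germinal centre, changed by -1.35 ± 0.34 on the log2 scale (SE), Gcsam, a signalling protein of these cells, by -2.65 ± 0.7 and Mef2b, one of their transcription factors, by -1.36 ± 0.45. Fas, Neil1 and Basp1 were not called (adjusted p = 0.341, 0.885 and 0.346). Without the 7 libraries 2 of the 7 were called. Gcsam (-1.38, adjusted p = 0.0752) and Mef2b (-1.0, adjusted p = 0.276) were not, though both stayed negative. Fewer germinal centre B cells, which a magnetic CD3 sort should remove, may have come through the sort with rapamycin. In R against NT without the 7 libraries all 7 genes of the set had negative fold changes, with a median of -0.97, against -0.03 in PS against NT and -0.29 in RO against NT. Lower expression per cell remains open, so the test cannot tell between the accounts.

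Whether the response is graded from oral to subcutaneous to loaded rapamycin was tested by step, without the 7 libraries. The mitosis mean differed by -0.11 between R and RO (exact two-sided permutation p = 0.706) and by -0.84 between rPS and R (exact p = 0.0476). The interferon mean differed by -0.18 (exact p = 0.0556) and by -0.23 (exact p = 0.0159). With 3 covariates from other-cell lists and all libraries, the mitosis median was -0.57 for R against RO and -0.5 for rPS against R. A graded response is left open, since the step from RO to R did not pass in the mitosis list, the lists were picked after their results were seen, and formulation, route and vehicle change together.

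List tests not described above are given here as values. In rPS against NT the 10 lists that camera called in no comparison included regulatory T cells with a median of -0.17 (adjusted p = 0.845), follicular helper T cells at -0.34 (adjusted p = 0.471), T helper 2 and 17 cells at -0.34 (adjusted p = 0.516) and T cell receptor activation at 0.24 (adjusted p = 0.688). Chemokine and adhesion receptors were at -0.30 (adjusted p = 0.112), fatty acid synthesis at -0.15 (adjusted p = 0.954), platelets at -0.60 (adjusted p = 0.601) and stroma at -0.20 (adjusted p = 0.517). The gamma delta list had a median of -0.12 and a mean of 0.0 while its test pointed higher (adjusted p = 0.927). Immediate early genes had 5 of 22 higher, with a median of 0.37 and adjusted p = 0.278. In R against RO the mean of the cholesterol list differed by exact permutation before adjustment (two-sided p = 0.00216), with a camera adjusted p of 0.000585 and adjusted p = 0.634 with an estimated correlation.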
